A study of Raphanus sativus with 12 samples.

How the data were processed

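Leaf blades of the radish (Raphanus sativus) material XHT were collected at 30 days after sowing, in vegetative growth, and at 120 days, in reproductive growth, from plants kept at 25 °C with 16 hours of light by day and at 23 °C in darkness by night, per the labels. Each of the 12 libraries was made from the mixed leaves of 3 plants, with 3 independent biological replicates per age and library type. At each age there were 3 input libraries, which are ordinary RNA-seq, and 3 immunoprecipitated (IP) libraries, in which RNA fragments carrying N6-methyladenosine (m6A) are enriched with an antibody. The groups and replicate numbers were taken from the sample titles.

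The submitters' processing notes name fastp and FastQC (read trimming and quality control), HISAT2 (alignment), StringTie (transcript quantification), HOMER (motif and peak annotation) and edgeR (differential expression), with no versions. The role given in brackets is each tool's usual use, and the role of each in this study is not given in the sources used here, nor are the genome build and the program that called the peaks. The 3 deposited tables were an expression table, a list of differential m6A peaks and a table joining the 2. The authors deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for the 6 input libraries, with 2 decimals, per the file headers. The expression table also holds the authors' fold change, p-value and q-value for each gene, per the file headers. Per the labels, the IP libraries belong to the same series, but no value per IP library was used here. For each peak, the authors deposited a log2 fold of 120 over 30 days, a p-value and an FDR, per the file headers. Whether that log2 fold was computed with the input libraries as a term is not given in the sources used here. Peaks were therefore described from the authors' comparison, with no test across libraries.

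FPKM values keep no read depth here: low values were not whole multiples of a common step, so the number of reads behind each value is unknown and no counting interval was given. Genes listed at exactly 0 may be failed estimates. Radish genes often have near-identical copies, and how reads shared between copies were assigned is not given in the sources used here, so values of single copies of a gene family are uncertain. Strand handling is not given either, so overlapping antisense genes could share reads.

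Differences in expression were tested with limma 3.58.1 in R 4.3.3, with eBayes and a mean-dependent trend, on log2(FPKM + 1), after keeping the genes with an FPKM of at least 1 in at least 3 of the 6 input libraries. All p-values were 2-sided and adjusted over the genes tested by Benjamini-Hochberg, with a threshold of 0.05 on the adjusted p. Fold changes are of 120 over 30 days on the log2(FPKM + 1) scale, which understates the change of low genes. Levels are means of FPKM ± SD over the 3 libraries of an age. The design written before the data were examined allowed for counts or for FPKM, and the FPKM branch was the one used. An exact test of a gene with 3 against 3 libraries cannot go below p = 0.1, so no exact test was used for single genes.

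There were 20 gene lists, fixed before the data were examined and matched by symbols or words in the gene descriptions of the deposited tables. Several matches were wider than the list names. ULTRAPETALA 1 was matched among the flowering promoters and UDP-glycosyltransferase 83A1 among the glucosinolate genes. The m6A demethylase list held only a DNA demethylase (ALKBH2-like) and 2 copies of alkB homolog 8. The shoot meristem list was made up mostly of CLE peptide genes, and the clock list held a phytochrome A-associated F-box protein. Lists with at least 3 tested members were compared with all other tested genes by camera (limma) with a preset correlation of 0.01, and the calls were repeated with an estimated correlation and with fry, which asks whether the members of a list move one way on balance and does not compare them with other genes. Each list count was also adjusted over the list alone.

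Named genes followed a rule set before the data were examined. It took the 8 greatest increases and 8 greatest decreases among called genes with no overlap between the ages, a mean FPKM of at least 10 in the higher group and an informative description. It added up to 4 members with the smallest p per list with called members, and all matched copies of set flowering and m6A genes (where there were more than 3 copies, the most abundant). Of the peaks in genes with an informative description, it took the 5 most increased and the 5 most decreased. No description matched LFY, AP1, CO, MTB, VIR, ALKBH9B or ALKBH10B by those names, though a gene described as methyltransferase-like protein 1 may be MTB.

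Differential peaks were counted at the authors' threshold, and the balance of higher and lower peaks was described with an exact 2-sided binomial test. Fisher's exact test (2-sided) was used for peak positions, for m6A direction against expression direction, and for the share of list members with a differential peak among the tested genes, adjusted over the 20 lists. Correlations across genes used 100000 permutations. Peak starts were listed counting from 0 (1807 of the 5476 listed starts lay exactly 1 base before the gene start and 0 on it) and are given here counting from 1. Coordinates are those of the deposited tables. The reference gene table at hand is of another assembly and was not used here.

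The fit was tested on simulated data for the comparison of 120 with 30 days over 21052 genes. With noise as in the data it recovered 31 of 100 genes changed by a log2 fold of 1 and 73 of 100 changed by 2, and called 8 unchanged genes. With noise at the tenth percentile it recovered all 100 genes of either size and called 9 unchanged genes. The simulation changed 200 genes, with independent noise and no common shift, while 9853 genes were called in the data. Its recovery and false calls therefore need not hold there. Alternatives covered the pseudocount, the filter, the scaling between libraries, the trend, the replicate block, each library left out, the authors' calls, stricter peak thresholds and array weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.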

Results

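The study mapped m6A, a methylated base in messenger RNA, in radish leaf blades to ask how it takes part in bolting and flowering, and compared vegetative plants of 30 days with reproductive plants of 120 days. Transcript levels came from 3 input libraries at each age. The m6A values were the authors' differential peaks. FPKM summed to between 636795 and 694436 per library, and the number of reads behind them is unknown. The 120-day libraries correlated with each other at Pearson's r of 0.971 to 0.985 on the log2 scale. Of the 30-day libraries, replicates 1 and 2 correlated at 0.944, while replicate 3 correlated with them at 0.895 and 0.835. The highest correlation between libraries of different ages was 0.853.

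At 120 days the leaves held far less transcript of FLOWERING LOCUS C (FLC), the repressor of flowering that is silenced by winter cold, and far more of SOC1 and of 1 copy of FLOWERING LOCUS T (FT), which promote flowering. All 3 FLC-like copies fell. Rsa10036313 (R03, 1772061 to 1775094) had 3.33 ± 1.23 FPKM at 120 days against 168 ± 41.3 at 30 days (SD, n = 3 each; log2 fold −5.29, limma adjusted p = 0.000583). Rsa10024990 (R02, 12773911 to 12779632) had 0.863 ± 0.995 against 26.6 ± 1.73 (log2 fold −4.02, adjusted p = 0.00195), and Rsa10013589 (R07, 21645173 to 21649952) had 31.5 ± 6.61 against 171 ± 82.1 (log2 fold −2.30, adjusted p = 0.00686). Both SOC1-like copies rose. Rsa10006202 (R04, 42438945 to 42442221) had 32.7 ± 5.07 against 0.77 ± 0.537 (log2 fold 4.29, adjusted p = 0.00104), and Rsa10039427 (R01, 1121341 to 1123716) had 36.9 ± 5.36 against 4.06 ± 2.46 (log2 fold 3.05, adjusted p = 0.00431). FT (Rsa10015765, R02, 33408838 to 33411177), the mobile signal that leaves send to the shoot tip, rose from 0.293 ± 0.295 to 10.3 ± 8.99 FPKM (log2 fold 2.79, adjusted p = 0.0144). Its 120-day values ranged from 2.51 to 20.11, and the call was lost without 120-day replicate 3 (adjusted p = 0.0545; 0.00544 to 0.0545 over the alternatives). The log2 fold was 2.16 and 3.45 without 120-day replicates 1 and 2. A second FT-like copy, Rsa10033877, lay below the filter and was not tested, with 6.5, 0 and 4.08 FPKM in the 30-day libraries and 0.57, 0 and 0.32 in the 120-day libraries.

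**Figure D1:**
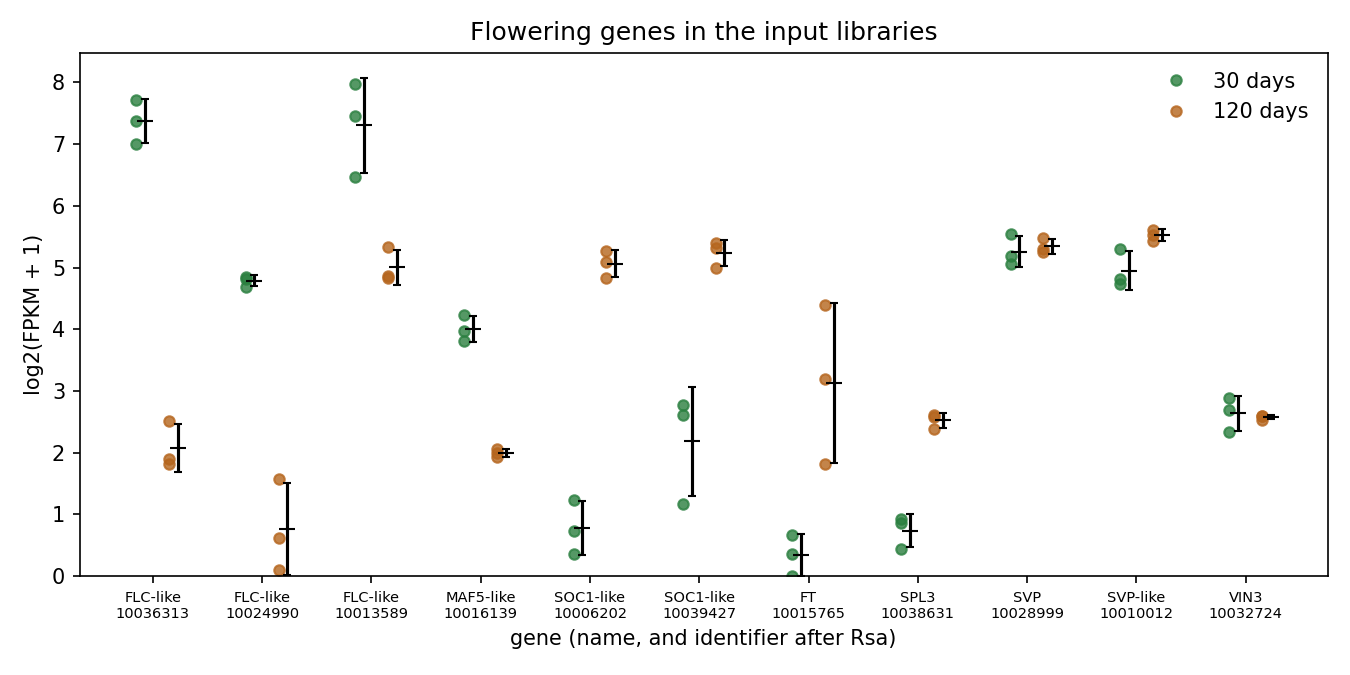
Level of 11 flowering gene copies on the log2(FPKM + 1) scale (y axis) in the 6 input libraries. Each point is a library, green at 30 days and brown at 120 days, and the black bars give the mean ± SD over the 3 libraries of an age. The FLC-like and MAF5-like copies lie lower at 120 days and the SOC1-like copies, FT and SPL3 higher, while SVP and VIN3 overlap between the ages.

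The 8 increases named next were the greatest at 120 days among called genes with no overlap between the ages, a mean of at least 10 FPKM in the higher group and an informative description. Chlorophyll a-b binding protein 2 (Rsa10029878), which carries antenna pigments, rose from 6.45 ± 3.6 to 2078 ± 417 FPKM (log2 fold 8.21, adjusted p = 0.000309), and chlorophyll a-b binding protein 1 (Rsa10038673) from 23.3 ± 23.9 to 864 ± 149 (log2 fold 5.94). The second had 1.64 FPKM in 30-day replicate 3, and its log2 fold was 4.75 without that library and 6.87 without 30-day replicate 2. Nitrate reductase (Rsa10023657), the enzyme that starts nitrate assimilation, rose from 0.61 ± 0.668 to 143 ± 7.79 (log2 fold 6.55), and beta carbonic anhydrase 1 (Rsa10014732) from 6.48 ± 4.29 to 497 ± 156 (log2 fold 6.20). BTB/POZ and TAZ domain-containing proteins 2 (Rsa10003709) and 1 (Rsa10019569) rose by log2 folds of 7.80 and 5.92. The other 2 of the 8 were a basic 7S globulin 2-like gene (Rsa10015247, 6.03, and 6.72 without 30-day replicate 2) and a proline-rich protein (Rsa10025726, 5.80, and 4.71 and 6.45 without 30-day replicates 3 and 1). By the same rule, the greatest decrease over all libraries was in early light-induced protein 1 (Rsa10005993), a chlorophyll-binding protein of light stress, at 6.39 ± 0.487 FPKM against 3123 ± 4680 (log2 fold −6.88, adjusted p = 0.0124), with 8507.46 FPKM in 30-day replicate 3 and 101.57 and 758.52 in the other 30-day libraries. Without that library its log2 fold was −5.24, behind genes such as glutaredoxin-S11 (Rsa10019917, −6.80), glutamine synthetase 1-4 (Rsa10018674, −5.48) and FLC-like Rsa10036313 (−5.47), and without 30-day replicate 2 it was −8.43. A second copy (Rsa10028070, log2 fold −5.84, adjusted p = 0.0456, and −3.72 and −7.89 without 30-day replicates 3 and 2) lost its call when the libraries were median-centred (adjusted p = 0.0851), when they were quantile-normalized (0.0873), with no filter, and when any 1 of the 120-day libraries or 30-day replicate 1 was left out. Cytosolic glutamine synthetase 1-4 (Rsa10018674), glutaredoxin-S11 (Rsa10019917) and tryptophan aminotransferase-related protein 4 (Rsa10016788) fell, with log2 folds of −6.09, −6.08 and −5.65. The glutamine synthetase had −6.75 and −6.79 without 120-day replicate 1 and 30-day replicate 2. FLC-like Rsa10036313, 1,8-cineole synthase 1 (Rsa10023120, −4.91) and vacuolar-processing enzyme gamma (Rsa10002434), a protease active in senescing tissue, completed the 8. The last had 64.0 ± 16.2 FPKM against 1850 ± 689 (log2 fold −4.80).

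In total 9853 of the 21435 genes tested differed between the ages, 1801 higher and 8052 lower at 120 days, and 4368 differed by at least 2-fold, 1258 higher and 3110 lower (limma, adjusted p under the threshold). The median gene was lower by a log2 fold of −0.446, while the 10 most abundant genes took 11.6% to 13.9% of the FPKM at 120 days and 4.76% to 6.56% at 30 days. After median centring 5156 genes were called, 2968 higher and 2188 lower, and after quantile normalization 5453, 2654 higher and 2799 lower. Lower calls were thus in large excess for the values as deposited, in slight excess after quantile normalization and in the minority after median centring. The values of the ages did not overlap in 13021 tested genes (60.7%), where 10% would do so by chance. Leaving out 120-day replicate 1, 2 or 3 left 6180, 4854 or 4864 calls, and leaving out 30-day replicate 3, the library that stood apart, gave 11363 (2197 higher and 9166 lower). The authors' deposited table called 5421 genes, 1946 higher and 3475 lower (at least 2-fold, p at most 0.05, q up to 0.16), and 4051 of its 4675 calls among the genes tested here (86.7%) were called here in the same direction.

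Of the fixed gene lists, 4 stood above the other genes at 120 days, those of photosynthesis, defence, glucosinolate synthesis and cell division (camera adjusted p = 4.95e-30, 2.64e-08, 5.25e-05 and 0.00547). None of these held with an estimated correlation (adjusted p = 0.473 with an estimated correlation for each of the 4). Of 82 photosynthesis genes, 47 rose and 2 fell over all genes tested, and 59 rose and 2 fell adjusted over the list alone. They included ribulose bisphosphate carboxylase small chain F1 (Rsa10035181), part of the enzyme that fixes carbon dioxide, at 8869 ± 1800 FPKM against 617 ± 198, and photosystem I reaction center subunit III (Rsa10015874) at 454 ± 33.3 against 63.4 ± 18.5. After quantile normalization 24 photosynthesis genes rose and 0 fell. The list took 17.8% to 22.1% of the FPKM at 120 days, and 6.02%, 6.97% and 4.25% in 30-day replicates 1, 2 and 3. Without 30-day replicate 3, 69 of its genes rose and 4 fell. Of 29 defence genes, 11 rose and 1 fell (the same numbers adjusted over the list alone; 9 and 4 without 30-day replicate 3), among them a defensin-like protein (Rsa10011352), 62.8 ± 7.3 against 1.17 ± 0.294 FPKM, and the defence regulator WRKY33 (Rsa10020317), 50.1 ± 14.5 against 15.3 ± 0.475.

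Of 30 genes of glucosinolates, the sulfur-containing defence compounds of the cabbage family, 11 rose and 4 fell (11 and 5 adjusted over the list alone; 11 and 1 after median centring and without 30-day replicate 3). A cluster of 4 indole glucosinolate O-methyltransferase 4 copies on R06, between 18499419 (Rsa10040292) and 18511049 (Rsa10040295), rose together, with log2 folds of 1.61 (Rsa10040295) to 2.23 (Rsa10040293), though reads could be shared between such near copies. Of 23 cell division genes, 8 rose and 5 fell (8 and 5 adjusted over the list alone; 8 and 0 after median centring). The genes that rose included the DNA replication licensing factors MCM2 (Rsa10024599) at 5.09 ± 1.22 against 1.29 ± 0.231 FPKM and MCM5 (Rsa10041681) at 2.86 ± 0.601 against 0.787 ± 0.146. Falls included cyclin-B1-2-like (Rsa10008368) at 44.1 ± 1.47 against 85.8 ± 11.1 and proliferating cell nuclear antigen 2-like (Rsa10037875) at 18.1 ± 4.24 against 43.0 ± 6.18. Both falls lost their call after median centring (limma adjusted p = 0.0705 and 0.0606) but not after quantile normalization (0.0275 and 0.0414).

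Flowering repressors fell more often than they rose: 20 of 33 fell and 3 rose over all genes tested, and 23 fell and 3 rose adjusted over the list alone. As a list they did not pass camera (adjusted p = 0.135, and adjusted p = 0.473 with an estimated correlation), and after median centring 8 fell and 3 rose. Besides the FLC copies, MADS AFFECTING FLOWERING 5-like (Rsa10016139), a relative of FLC, fell to 3.0 ± 0.18 from 15.2 ± 2.39 FPKM (log2 fold −2.01), and SUPPRESSOR OF FRI 4 (Rsa10039644), which takes part in FLC activation, to 7.65 ± 0.308 from 17.5 ± 0.492 (log2 fold −1.10). The repressor SVP (Rsa10028999) had 39.7 ± 3.45 against 37.6 ± 6.97 (adjusted p = 0.696), and SVP-like Rsa10010012 rose to 45.0 ± 3.07 from 30.4 ± 7.12 (log2 fold 0.57, adjusted p = 0.0466; 0.000512 to 0.132 over the alternatives), a call lost when any library but 30-day replicate 3 was left out. Of 35 flowering promoters, 4 rose and 11 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.421), with 4 and 13 without 30-day replicate 3. After median centring 6 rose and 4 fell, so their median turned from −0.211 to 0.226. Squamosa promoter-binding-like protein 3 (Rsa10038631) rose to 4.77 ± 0.475 from 0.687 ± 0.295, while its relative protein 4 (Rsa10027473) fell to 0.443 ± 0.172 from 6.80 ± 3.17, and FD-like (Rsa10026866), the partner of FT, to 0.487 ± 0.304 from 4.61 ± 0.702. AGL8, the FRUITFULL gene, had 4 copies, and the most abundant (Rsa10019670) had 13.6 ± 9.41 against 15.8 ± 9.1 (adjusted p = 0.814).

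Of 53 clock and photoperiod genes, 21 fell and 1 rose (the same numbers adjusted over the list alone; camera adjusted p = 0.599), and 5 fell and 3 rose after median centring. Phytochrome B (Rsa10032063), a red light receptor, had 4.11 ± 0.387 against 9.87 ± 0.414 FPKM (log2 fold −1.09, adjusted p = 0.00327), and ELF4-LIKE 1-like (Rsa10007109), ELF4-LIKE 2 (Rsa10022832) and REVEILLE 5 (Rsa10025651) had log2 folds of −1.52, −1.74 and −1.45. This list was touched by 30-day replicate 3: the 2 GIGANTEA copies had 1.35 (Rsa10001141) and 0.9 (Rsa10040162) FPKM there against 14.26 and 15.4, and 8.33 and 7.35, in the other 30-day libraries. With it their log2 folds of −0.75 and −0.68 did not pass (adjusted p = 0.443 and 0.39), and without it both passed (adjusted p = 0.0047 and 0.0046), as 28 of the list fell and 3 rose. Of 26 gibberellin genes, 11 fell and 5 rose (the same numbers adjusted over the list alone; camera adjusted p = 0.554), and 5 fell and 5 rose after median centring. The gibberellin receptors fell, with GID1B (Rsa10027754) at 1.10 ± 0.269 against 16.9 ± 9.36 and GID1A-like (Rsa10010079) at 6.01 ± 0.316 against 27.5 ± 7.2, while gibberellin-regulated protein 13-like (Rsa10034565) rose to 45.7 ± 24.5 from 2.83 ± 2.03. Of 13 vernalization and Polycomb genes, 2 fell (EZA1-like Rsa10007003, log2 fold −0.71, and MSI1 Rsa10032764, −0.49), 0 did so adjusted over the list alone, and after median centring 2 rose and 0 fell (camera adjusted p = 0.598). Without 30-day replicate 3, 4 fell and 1 rose. Both falls were lost under either other scaling and when any 1 of the 120-day libraries or 30-day replicate 1 was left out, and that of MSI1 also with a replicate block (Rsa10032764, adjusted p = 0.0514). VERNALIZATION INSENSITIVE 3 (Rsa10032724), which marks exposure to cold, had 4.96 ± 0.14 against 5.31 ± 1.2 (adjusted p = 0.782). Of the 16 matched floral organ identity genes 1 was high enough to test and did not pass.

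Of 6 m6A writer genes, 2 fell and 0 rose (the same adjusted over the list alone; camera adjusted p = 0.615), and 0 passed after median centring. Those 2 were copies of HAKAI, of which 4 were matched and 2 tested (Rsa10008001, 17.2 ± 0.694 against 27.8 ± 2.25 FPKM, log2 fold −0.66, adjusted p = 0.00934, and 0.243 after centring; Rsa10030002, log2 fold −0.55). The call of the second copy was also lost when any 1 of the 120-day libraries or 30-day replicate 1 was left out. The methyltransferase MTA-like (Rsa10009074) had 8.40 ± 0.495 against 10.03 ± 1.47 (log2 fold −0.22, adjusted p = 0.251, and 0.21 after median centring), and the 3 FIP37-like copies had log2 folds of −0.65 (Rsa10030202, adjusted p = 0.0761), −0.24 (Rsa10030971) and −0.10 (Rsa10028314), the last 2 being 0.19 and 0.34 after centring. Of the 3 genes matched as demethylases 2 fell, ALKBH2-like (Rsa10028979, log2 fold −1.28) and alkB homolog 8 (Rsa10015864, −0.44), both also adjusted over the list alone and neither after median centring (camera adjusted p = 0.554); leaving out any library ended the second. Of 8 reader genes, 3 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.859), and 1 fell and 1 rose after centring. YTH domain-containing protein 1-like (Rsa10010171) had 4.63 ± 0.417 against 11.1 ± 0.699 (log2 fold −1.11), and YTH domain-containing family protein 2-like (Rsa10014930) 2.32 ± 0.475 against 1.10 ± 0.185 (log2 fold 0.65, lost when any 1 of the 120-day libraries or 30-day replicate 1 was left out). Methyltransferase-like protein 1 (Rsa10029339), chosen after its values were seen, lay outside the fixed writer list but may be the writer subunit MTB by its description. It had 3.90 ± 0.381 against 11.7 ± 1.69 (log2 fold −1.37, adjusted p = 0.00304, and 0.00687 after centring).

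Of 27 senescence genes, 9 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.742), and 5 fell and 2 rose after median centring. Without 30-day replicate 3, 9 fell and 5 rose. The chlorophyll breakdown genes STAY-GREEN 1-like (Rsa10025626) and pheophytinase (Rsa10036156) fell: the first had 3.65 ± 0.822 against 26.1 ± 13.6 FPKM and the second 50.98 ± 4.47 against 224 ± 98.4, each highest in 30-day replicate 3 (41 and 333.75). Of 23 cold and dehydration genes, 4 rose and 5 fell (the same numbers adjusted over the list alone; 4 and 2 after median centring; camera adjusted p = 0.474). KIN2-like (Rsa10019565) rose to 18.7 ± 10.5 from 0.277 ± 0.112, and dehydrin ERD14-like (Rsa10030694) fell to 169 ± 71.3 from 1812 ± 1120, with 3097.03 in 30-day replicate 3, without which 10 of the list fell. Of 238 cytosolic ribosomal protein genes, 79 fell and 5 rose (55 and 4 adjusted over the list alone; camera adjusted p = 0.421), but 11 fell and 14 rose after median centring, and 115 fell and 6 rose without 30-day replicate 3. Of 39 heat shock genes 15 fell (the same number adjusted over the list alone; camera adjusted p = 0.777), 4 fell and 3 rose after centring, and 19 fell and 2 rose without 30-day replicate 3. Heat shock protein 90-1-like (Rsa10010038) fell by 1.35 on the log2 scale.

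Of 12 vascular genes 4 fell, among them the phloem sucrose transporter SUC2 (Rsa10040167, 16.2 ± 6.53 against 56.5 ± 25.3 FPKM, a call lost without 120-day replicate 2 or 3 or 30-day replicate 1 or 2), and of 10 meristem genes 4 fell, all of them CLE peptide genes. These were 0 and 4 adjusted over the list alone, and 0 of either list after median centring (camera adjusted p = 0.742 and 0.859). Of 24 epidermis, wax and stomatal genes, 1 rose and 4 fell (0 and 1 adjusted over the list alone, 2 and 1 after centring, and 2 and 9 without 30-day replicate 3; camera adjusted p = 0.554), with ECERIFERUM 26-like (Rsa10027371), a wax synthesis gene, at 52.0 ± 8.56 against 148 ± 18.9. Camera, which compares a list with all other genes, pointed up for several lists with a negative median, those of flowering promoters, vernalization, gibberellin, m6A readers, senescence, cold response and epidermis, and none of these passed.

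**Figure D2:**
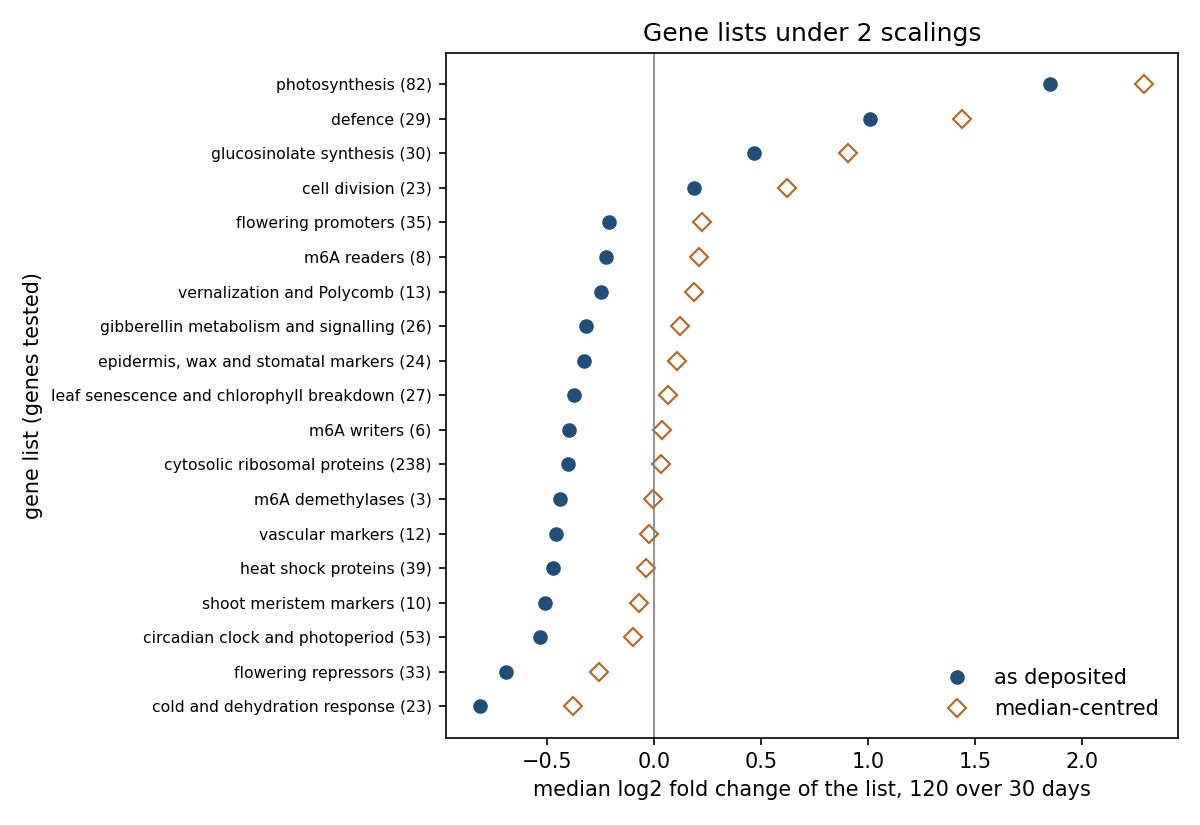
Median log2 fold change of 120 over 30 days (x axis) of each gene list (y axis, number of genes tested in brackets), from the FPKM as deposited (filled circles) and after median centring (open diamonds). Photosynthesis, defence, glucosinolate synthesis and cell division lie above 0 under both, while flowering promoters, m6A readers and several other lists change sign.

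The m6A peaks that differed were nearly all higher at 120 days. The authors' deposited table listed 5476 differential peaks in 5211 genes, 5300 higher (96.8%) and 176 lower (exact binomial p at or below 1e-300 against equal numbers). Peaks of the same libraries are not independent, so this p describes the imbalance alone and says nothing of spread between samples. Most differences were small: the median log2 fold was 0.504, with quartiles of 0.369 and 0.692, over a range of −10.4 to 8.3. Only 560 peaks had a log2 fold of at least 1 in size, 472 higher and 88 lower. Among peaks at an FDR under 0.01, 4458 of 4538 were higher (98.2%). The folds, p and FDR are the authors', and spread between IP replicates was not analysed here. Listed peaks had an authors' p of up to 0.049 and an FDR of up to 0.0912, by a test not given in the sources used here.

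**Figure D3:**
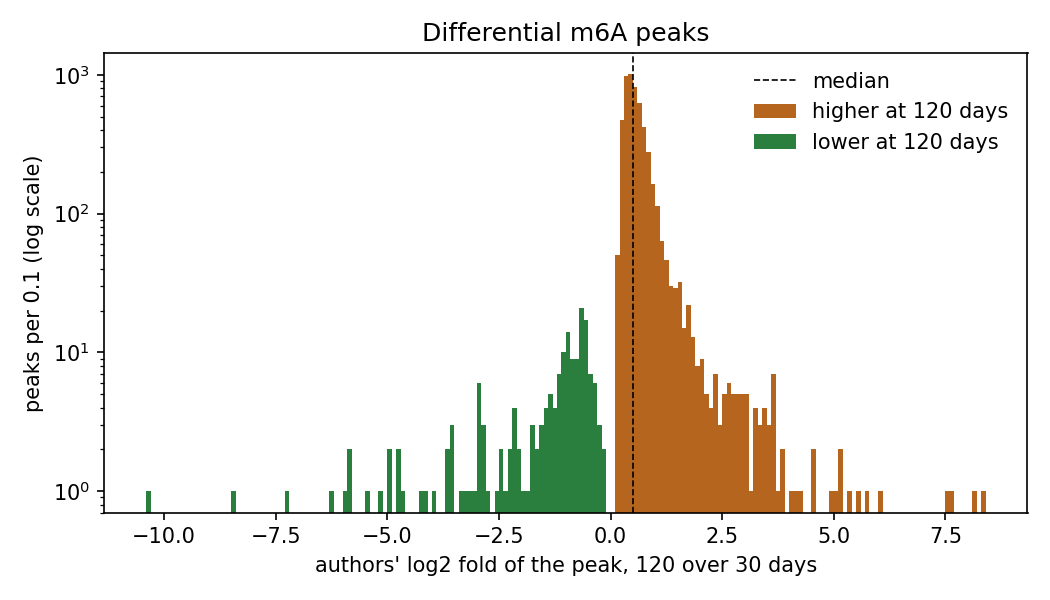
Number of differential m6A peaks (y axis, log scale) per 0.1 of the authors' log2 fold of 120 over 30 days (x axis), brown where higher and green where lower at 120 days. The 5300 higher peaks pile up around the median of 0.504 (dashed line), and the 176 lower peaks spread down to −10.4.

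The most increased named peak was in the mitochondrial aspartate aminotransferase gene (Rsa10016561), an enzyme of amino acid metabolism, on exons at R04 36553488 to 36554099 (log2 fold 8.3). The gene had a further peak among the 5 most increased, at 36552961 to 36553428 (5.3), and a transcript of 11.6 ± 1.02 FPKM at 120 days against 7.87 ± 2.45 (adjusted p = 0.1). Increased exonic peaks also lay in a probable polygalacturonase (Rsa10002725, R04 48720378 to 48721076, 6.06), inositol oxygenase 4 (Rsa10036737, R04 3652700 to 3653195, 5.53) and syntaxin-22 (Rsa10000544, Scaffold2559 1756 to 2738, 5.18). The most decreased named peaks were exonic in coatomer subunit gamma (Rsa10000742, Scaffold1927 770 to 1115, −8.46), replication protein A 70 kDa subunit A-like (Rsa10004003, R02 18338485 to 18339049, −7.21), beta-amylase 6 (Rsa10038527, R01 6317772 to 6318240, −5.95) and beta-glucosidase 15 (Rsa10000617, Scaffold2359 1116 to 1472, −5.89), and in the 3′ UTR of endonuclease III homolog 1 (Rsa10032272, R03 8479695 to 8480155, −5.83). Of these 5 genes none passed the expression test (adjusted p = 0.0631 to 0.548), while of the 4 with increased peaks inositol oxygenase 4 (Rsa10036737) rose (log2 fold 3.19), and the polygalacturonase (Rsa10002725, −0.61) and syntaxin-22 (Rsa10000544, −0.94) fell. Inositol oxygenase 4 had only 0.493 ± 0.527 FPKM at 30 days. Beta-glucosidase 15 had 1.14 FPKM at 120 days against 0.81, and endonuclease III homolog 1 had 0.933 against 2.07. The peak folds of these genes rest on little transcript, while the other genes named here had 4.007 FPKM or more at either age. The authors' FDR was 0.0324 for the beta-amylase 6 peak and 0.0182 for that of endonuclease III homolog 1.

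Among the flowering genes, MADS AFFECTING FLOWERING 5-like (Rsa10016139) carried a higher peak in its 3′ UTR (R01 41304844 to 41306265, log2 fold 0.84) while its transcript fell, as did SUPPRESSOR OF FRI 4 (Rsa10039644, 3′ UTR, R06 13699713 to 13700739, 0.73). SVP-like (Rsa10010012, R04 33172264 to 33175636, annotated by the authors as 3′ UTR) had a log2 fold of 0.31. That interval spans most of the gene (33172264 to 33175958), so it does not place the peak within the 3′ UTR. In the m6A machinery, higher peaks lay in HAKAI (Rsa10008001, exonic, 0.40), FIP37-like (Rsa10028314, 3′ UTR, 0.79), CPSF30-like (Rsa10040349, exonic, 0.55) and 2 YTH domain-containing family protein 2-like readers (exonic, Rsa10014930, 0.64, and Rsa10021705, 0.44). Of these 5 genes, Rsa10014930 rose in expression, HAKAI and CPSF30-like (Rsa10040349, log2 fold −0.66, adjusted p = 0.0117) fell, and the other 2 did not pass. The FLC-like, SOC1-like and FT copies named above were not among the genes with differential peaks. Several had little transcript at 30 or 120 days, such as FLC-like Rsa10024990 (0.863 FPKM at 120 days) and FT (0.293 at 30 days). FLC-like Rsa10013589, in contrast, had 31.5 FPKM at 120 days and 171 at 30 days. Unchanged peaks were not listed, so this absence does not show that m6A on these genes stayed the same. Vacuolar-processing enzyme gamma (Rsa10002434, exonic, R02 76560 to 76937) had a peak lower by a log2 fold of −4.78, close to the −4.80 of its transcript.

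Differential peaks gathered towards the 3′ ends of genes. The authors' annotation put 3449 peaks (63%) on exons, 1890 (34.5%) in 3′ UTRs and 137 (2.5%) in 5′ UTRs, and the median peak centre lay at 0.867 of the gene span counted from the 5′ end. Exonic peaks lay about as far along as 3′ UTR peaks, with medians of 0.877 and 0.861. Whether exonic peaks lie in coding sequence was not assessed. Lower peaks were in 5′ UTRs more often than higher peaks, at 10.2% (18 of 176) against 2.25% (119 of 5300), and shares in 3′ UTRs were 35.2% and 34.5% (Fisher's exact test over the 3 classes, 2-sided, p = 5.43e-07, and 0.00926 at an FDR under 0.01).

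Genes with higher m6A that were called in expression were mostly lower, but so were called genes without a differential peak. The latter numbered 5246 lower and 1585 higher. Of the 5004 tested genes with a differential peak, 2806 were called lower and 216 higher, and the rest did not pass. Of the genes whose peaks all went one way and whose expression was called, 2764 with higher m6A were lower and 200 higher in expression (93.3% lower), against 38 lower and 16 higher with lower m6A (70.4% lower). The odds ratio was 0.172 (95% interval 0.0917 to 0.337, Fisher's exact test, 2-sided, p = 5.01e-07), and 0.0761 to 0.176 with any 1 library left out. The share lower among genes with lower m6A was 55.6% to 70.2% with a library left out, 45% in genes with a mean of at least 10 FPKM and 40% with the authors' expression calls. After median centring, which moves most genes up, the counts were 716 lower and 438 higher with higher m6A against 10 lower and 29 higher with lower m6A (odds ratio 0.211, Fisher's exact p = 7.1e-06, chosen after the data were seen). Across 5004 genes the correlation of peak fold and expression fold was small (Spearman's rho −0.112, permutation p = 1e-05, the smallest 100000 permutations can give; Pearson's r −0.0603, permutation p = 4e-05; adjusted over the 2, p = 2e-05 and 4e-05), and genes are not independent replicates. If the authors' peak fold has an input term, the 2 measures share the input libraries, and part of the relation is then built in. The authors' deposited joined table marked 650 peaks as higher in a gene lower in expression, 98 higher with higher, 18 lower with higher and 12 lower with lower.

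Differential peaks were common on ribosomal protein genes and rare on photosynthesis genes. Of 238 cytosolic ribosomal protein genes 95 carried one (39.9% against 23.2% of the other tested genes, odds ratio 2.2, Fisher's exact test adjusted over the lists, p = 2.3e-07), all of them higher. Of 82 photosynthesis genes 4 did (4.88%, adjusted p = 9.92e-05), 3 of them with lower m6A, such as photosystem I reaction center subunit III (Rsa10015874, 3′ UTR, R08 12953976 to 12954296, log2 fold −0.32). None of 27 senescence genes did (adjusted p = 0.00707), and 1 of 30 glucosinolate and 1 of 29 defence genes did (adjusted p = 0.0308 each, lost at a peak FDR under 0.01, with 0.0796 each). Flowering repressors had 11 of 33 (adjusted p = 0.388), flowering promoters 8 of 35 (adjusted p = 1), clock genes 10 of 53 (adjusted p = 0.691) and cell division genes 9 of 23 (adjusted p = 0.206), all without passing. Cell division passed among genes with a mean of at least 10 FPKM (odds ratio 14.6, adjusted p = 0.0163). The other 11 lists did not pass either. Only differential peaks were listed, so a gene without one may carry no m6A peak or an unchanged one. These shares therefore cannot separate a change of m6A from which transcripts carry m6A or could be measured.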

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

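The number of genes called under other splits of the libraries, given last, was a test planned before the data were examined, and no test here was chosen after a result was seen.

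The peak table held 11 genes, with 11 differential m6A peaks, for which the expression table used here had no values, so these peaks stood outside every comparison with expression. They included sugar transport protein 9 (Rsa10031530, exonic, R06 3208907 to 3209523, log2 fold 2.55), 40S ribosomal protein S13-2 (Rsa10029623, exonic, R07 10415176 to 10415385, 5.04), calcium-dependent protein kinase 24-like (Rsa10016605, 3′ UTR, R04 36886184 to 36886751, 0.44) and WAT1-related protein At5g13670 (Rsa10025164, exonic, R02 11777217 to 11777723, −0.95), chosen after their values were seen. No explanation for their absence was tested.

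The 6 input libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 9853 genes and the highest of the other splits 0, and 4368 against 0 at 2-fold or more, so 1 of the 10 splits reached each real count. For the gene lists the real split called 4 and the highest of the others 6, and 7 of the 10 splits called at least 4 lists.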

How the results depend on the processing

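Array weights, lists without members of another protein, centred or quantile-normalized expression beside m6A, and the correlation in genes with higher or lower peaks alone were alternatives chosen after the data were seen. The others were planned. The count of 9853 genes fell to 5156 with median centring and to 5453 with quantile normalization, with 57.6% and 48.7% of the calls higher in place of 18.3%. Of the original calls 3986 and 4513 were shared in the same direction and 0 were called with the sign turned. At 2-fold or more the share higher turned from 28.8% to 66.8% and 57.4%. These alternatives move the median fold of −0.446 towards 0 by construction. Array weights gave 16557 calls, and the cause was not tested. The authors' calls numbered 5421 (35.9% higher) and need a 2-fold change and an unadjusted p of at most 0.05 (q up to 0.16). Leaving out each library gave 4854 to 11363 calls, more than 9853 without 30-day replicate 2 or 3, with the cause untested, and 3201 to 5064 at 2-fold or more. The pseudocount, the filters and the trend moved the count by less than 1.5 times.

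The 4 lists called by camera fell to 0 with an estimated correlation and became 8 with fry, which asks another question. The estimated correlations were 0.486 for photosynthesis, 0.344 for defence, 0.164 for glucosinolate synthesis and 0.0899 for cell division, all above the preset 0.01. How much of the fall to 0 they account for was not tested. Differential peaks numbered 560 at a log2 fold of at least 1 and 2077 in genes not differing in expression, by construction, with 84.3% and 95.9% higher. Lists with more or fewer peaks than other genes fell from 5 to 3 at a peak FDR under 0.01 (fewer peaks). The odds ratio of m6A with expression kept its direction in every alternative run (0.0659 to 0.248), whereas Spearman's rho was −0.204 in genes with a mean of at least 10 FPKM and 0.166 in genes with lower peaks.

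No called named gene was called with the other sign under any alternative run, but some that did not pass changed sign, such as MTA-like (Rsa10009074, −0.22 to 0.21 with median centring). Median centring left 78 on their side of the threshold, ended 22 calls and added 1, and quantile normalization left 81, ended 19 and added 1. Leaving out single libraries ended 4 to 21 calls.

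Whether the replicate numbers pair the samples is not settled. Deviations of same-numbered libraries correlated at 0.27, 0.14 and 0.081, and those of differently numbered libraries at −0.2 to 0.031. With a replicate block 8608 genes were called (1733 higher, 6875 lower), and 7 of the named genes lost their call. Each library correlated best with its own number, a hint from the data and not from the design. Read depth is unknown, so its limit on low genes was not assessed.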

Other observations

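The tests of explanations, their bounds, the pathways and the correlation in genes with lower peaks were chosen after the results they measure were seen, while Spearman's correlation over all genes and in genes with a mean of at least 10 FPKM was planned.

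Among 121 KEGG pathways of the deposited annotation, 36 passed camera, 29 upward and 7 downward at 120 days, and none with an estimated correlation (lowest adjusted p = 0.399 with an estimated correlation). Upward, besides photosynthesis, stood carbon fixation (44 of 114 genes rose and 19 fell, camera adjusted p = 2.23e-10), porphyrin and chlorophyll metabolism (22 of 74 rose and 13 fell, 2.1e-06), nitrogen metabolism (17 of 50 rose and 16 fell, 0.00208) and sulfur metabolism (9 of 52 rose and 11 fell, 0.0037). Since 30-day replicate 3 was low in light-harvesting transcripts, the pathways were counted without it too, with 50 up and 22 down in carbon fixation, 30 and 16 in porphyrin and chlorophyll, 20 and 17 in nitrogen and 16 and 13 in sulfur metabolism. After median centring the last 2 had 20 up and 8 down, and 13 and 2. Downward stood, among the 7, the spliceosome (166 of 318 fell and 1 rose, adjusted p = 0.00159), mRNA surveillance (130 of 241 fell and 2 rose, 0.0028), ribosome biogenesis (90 of 161 fell and 1 rose, 0.00342), RNA transport (177 of 354 fell and 7 rose, 0.0124) and autophagy (40 of 67 fell and 0 rose, 0.00168). After median centring these 5 pathways still had more falls than rises, with 27 and 8 in the spliceosome and 11 and 0 in autophagy. Over all 21435 genes tested, 2188 fell and 2968 rose after centring. The spliceosome thus had few rises, and its share of falls was no greater than that of all genes. The same held for the share of falls in ribosome biogenesis (11 of 161) and RNA transport (34 of 354). In mRNA surveillance (29 of 241) and autophagy (11 of 67) that share was greater than over all genes.

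Methylthioalkylmalate synthase 1-like (Rsa10019680), which lengthens the side chain, had 246.79, 54.6 and 69.46 FPKM in the 120-day libraries and 116.49, 24.93 and 251.58 in the 30-day libraries, and its regulator MYB28-like (Rsa10033628) had 56.08, 12.59 and 17.86, and 56.24, 11.73 and 74.83. Neither differed between the ages (limma adjusted p = 0.928 and 0.536). Both genes were chosen after their values were seen.

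In 30-day replicate 3, light-harvesting transcripts were far below the other 30-day libraries, with 5.88 FPKM of chlorophyll a-b binding protein 4 (Rsa10007770, chosen after its values were seen) against 271.01 and 459.14, and early light-induced protein was far above them. An incorrect age label is argued against: its highest correlation with a 120-day library was 0.741, below its lowest of 0.835 with a 30-day library, a test put in after another had fallen short of its bound (78.5% of 4751 genes lay nearer to the other 30-day libraries, with 80% set). Less green tissue as the whole cause is argued against as well, since 7 of 57 abundant photosynthesis genes were at or above their mean in the other 30-day libraries and the log2 ratios ran from −5.68 to 1.51. A harvest at another time of day may explain it: all 11 morning genes of the clock (REVEILLE and CCA1 genes) were above the other 30-day libraries, by a median log2 ratio of 1.27, and 15 of 19 evening genes below, by a median of −0.563, a difference of 1.83. Stress at harvest and differences between plants stay open and untested, and the labels give no time of day. Time of day could therefore also differ between the ages, which was not tested. Morning genes, chosen after their values were seen, went both ways with age. REVEILLE 8 (Rsa10018441) had 0.34 to 0.6 FPKM at 120 days against 2.49 to 21.67 at 30 days. REVEILLE 2 (Rsa10016855) had 163.76 to 224.57 against 33.11 to 137.38.

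That 96.8% of the differential m6A peaks were higher at 120 days could come, among other sources, from a general rise of m6A with age or from the scaling of the input. No value per IP library was used, so differences between the IP libraries of the ages were not assessed. The median writer gene changed by a log2 fold of 0.048 relative to the median gene (SE 0.1). This lay below the median peak fold of 0.504, but it cannot decide on writer levels as the source. The rise in writer transcript that such a peak fold would need is unknown, and the list held no gene matched as MTB or VIR. Whether a fall of the typical gene's share of the input is the source stays open: 60% of the peaks had a log2 fold above the input's median fall of 0.446, but the list holds only peaks past the authors' threshold, so this share decides nothing. Whether each peak carries its own gene's input change cannot be told apart from no such link, as Spearman's rho of −0.112 lay between the bounds set for either, while −0.204 in genes with a mean of at least 10 FPKM was past the bound for such a link and 0.166 in genes with lower peaks was not. A biological rise of m6A in reproductive leaves stays open, as the authors' scaling is not given in the sources used here.

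The excess of lower genes at 120 days may be in part a matter of shares. The 102 genes that reach 1000 FPKM in any library took 30% of the FPKM at 120 days and 14.8% at 30 days. With them left out of the library totals, the median log2 fold moved from −0.446 to −0.27, and with the 1875 genes reaching 100 FPKM left out, to −0.103. A true lowering of most transcripts and a shift of shares towards abundant transcripts cannot be told apart, since FPKM hold no absolute amounts and −0.27 lay between the bounds set for either.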
